A study of Homo sapiens with 8 samples.

How the data were processed

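RNA sequencing libraries were made from HEK293T cells that stably carried the PRADA construct, grown in culture or as xenografts in mice. Each of the 4 groups (unlabelled and labelled, in culture and in xenografts) held 2 libraries. Per the labels' protocols, RNA that had taken up the label was enriched and ribosomal RNA was depleted before sequencing. The groups and replicate numbers of the culture libraries came from the labels. The xenograft columns of the count table carry a number shared by both libraries of a group and a letter, L or R, so that each group may be a pair of tumours from a single mouse. The p-values therefore measure the spread between these libraries, which may be technical.

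The deposited values were raw counts per gene, whole numbers with no normalization. Per the file headers, they were made with featureCounts 1.6.4 against GENCODE release 44, counting properly paired fragments without regard to strand, leaving out fragments that align to several places and fragments that overlap several genes. Per the submitters' processing notes, reads were aligned with STAR 2.7.9a to GRCh38 and DESeq2 1.42.0 was used. Whether mouse reads were removed from the xenograft libraries is not given in the sources used here. Genes with a near-identical copy, such as nuclear pseudogenes of mitochondrial DNA, small nuclear RNAs and 7SL or 7SK copies, and genes that overlap another gene on either strand, are therefore uncertain: part of their reads was dropped or may come from the other strand. The tables held 62700 genes, all with a symbol. Total counts ranged from 26676373 to 36580738 per library, and all 8 sample columns were used. Biotypes and transcript sequences came from GENCODE release 29, which held 58207 of the identifiers; coordinates are those of release 44 on GRCh38.

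Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with its quasi-likelihood F-test (glmQLFit and glmQLFTest), TMM normalization, filterByExpr and Benjamini-Hochberg adjustment, and calls were made at an adjusted p under 0.05. Adjusted p-values in the text are from this test unless another tool is named. Labelled and unlabelled libraries were compared within culture (27900 genes passed the filter) and within xenografts (26450 genes). The difference between these labelling effects was tested as an interaction over all 8 libraries (29733 genes), and unlabelled xenografts were compared with unlabelled culture (28260 genes). Log2 fold changes are given with their standard error, and CPM are TMM-normalised means with SD unless said to be shares of the total. Shares of counts were compared by exact two-sided permutation tests. The area under the ROC curve (AUC) described how well the log2 fold change parted the genes of mitochondrial DNA from nuclear genes, with no p-value, since genes are not independent replicates.

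The 26 gene lists, the named-gene rule, the tests and the alternative settings were fixed before the data were examined. The lists were the 13 mRNAs, 2 rRNAs and 22 tRNAs of mitochondrial DNA, nuclear pseudogenes of mitochondrial DNA, nuclear-encoded subunits of oxidative phosphorylation, mitochondrial ribosomal proteins, matrix enzymes, cytosolic ribosomal proteins, nuclear long noncoding RNAs, small nuclear RNAs, RNA polymerase III transcripts, histones, secretory pathway genes, hypoxia targets, glycolysis, G2/M genes, S-phase genes, integrated stress response, oxidative stress, heat shock, immediate early genes, p53 targets, and markers of fibroblasts, of endothelium, of immune cells, and of erythroid cells, muscle and skin. The list of small nuclear RNAs also held small nucleolar and Cajal body RNAs. That of matrix enzymes also held chaperones and mitochondrial gene expression factors, and both lists go by the short names below. A few stress genes, such as ATF3, DDIT4 and SLC7A11, stood on more than 1 list. Each list was tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 26 lists, and again with an estimated correlation; members were also counted with p-values adjusted over the list alone.

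Genes were named by a rule. For each labelling comparison these were the mRNAs and rRNAs of mitochondrial DNA and its tRNAs as a group; the 10 nuclear genes with the largest rise and the 10 with the largest fall among those called, with a mean log2 CPM of at least 1 and both libraries of a group above both of the other; and up to 4 members of each list with the smallest p. The interaction and the comparison of xenografts with culture used the last 2 parts. Genes named outside the rule are said to have been chosen after their values were seen. Not all genes that the rule named have their values printed. The result of 1 of them is not reported here, and that gene stays in the counts of its list.

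The tests were tried on simulated counts with 200 changed genes per comparison. At a log2 fold of 1 and of 2, the test recovered 47 of 88 and 70 of 112 changed genes in the culture design (27900 genes), 58 of 99 and 99 of 101 in the xenograft design (26450 genes), 46 of 109 and 56 of 91 for the interaction (29733 genes), and 39 of 102 and 73 of 98 for xenograft against culture (28260 genes). False calls numbered 2, 2, 3 and 10. The simulated counts had no piled-up reads and the same dispersion in all groups. These numbers may therefore not hold for the comparisons that use unlabelled culture.

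Alternatives were DESeq2 size factors, total counts only, TMM over genes not on mitochondrial DNA, no filter, a filter at a CPM of 1 in 2 libraries, the DESeq2 Wald test (version 1.42.0), a replicate block, a single fit over all 8 libraries, a minimum absolute log2 fold change of 1, and leaving out each library in turn. A correction for GC content, a division of piled-up counts and blocks on the letters L and R were added after the data had been seen. Shares, permutation tests and figures were made with python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.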

Results

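The study mapped RNA near an enzyme placed in the mitochondrial matrix, in cultured cells and in tumours grown from the same cells. HEK293T cells, an established human embryonic kidney line, stably carried PRADA, a V5-tagged labelling enzyme targeted to the matrix. All cells and animals were given 4-thiouridine (s4U), a uridine analogue that cells build into new RNA, and alkyne phenol (AP), the substrate of the labelling reaction. Labelled samples also received D-amino acid for 30 min, which starts the reaction; unlabelled samples did not. Culture used 100 µM s4U for 5 h, 0.5 mM AP and 10 mM D-amino acid. Xenografts in the hind legs of immunodeficient mice used 430 mg/kg s4U for 5 h, 30 mM AP, 100 mM D-alanine and 100 mM D-phenylalanine, so the doses differed between the settings.

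Each of the 4 groups held 2 libraries of enriched, ribosomal-RNA-depleted RNA. Counts on genes totalled 34060161 and 28708320 in unlabelled culture, 32895951 and 33465776 in labelled culture, 26676373 and 36580738 in unlabelled xenografts (libraries L and R), and 31107567 and 26858033 in labelled xenografts (L and R). Replicates of labelled culture, unlabelled xenografts and labelled xenografts differed by more than sampling of independent reads gives, with a chi-square per degree of freedom of 24.4, 7.18 and 6.02. The value of 16.4 in unlabelled culture is raised by piled-up reads and was not read this way. Low counts in the unlabelled culture libraries had a second peak, at 9 reads per gene (598 genes) in replicate 1 and at 5 reads (842 genes) in replicate 2. In the other 6 libraries 1 read was the most frequent low count, with 3108 to 4028 genes. Genes with a single read numbered 796 and 793 in unlabelled culture and between 3108 and 4028 in the other libraries. The biological coefficient of variation that edgeR estimated was 0.199 in culture and 0.0651 in xenografts. The culture value includes the unlabelled libraries with piled-up reads, and each xenograft group may be a single mouse. These values therefore do not compare biological variation between the settings.

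**Figure D1:**
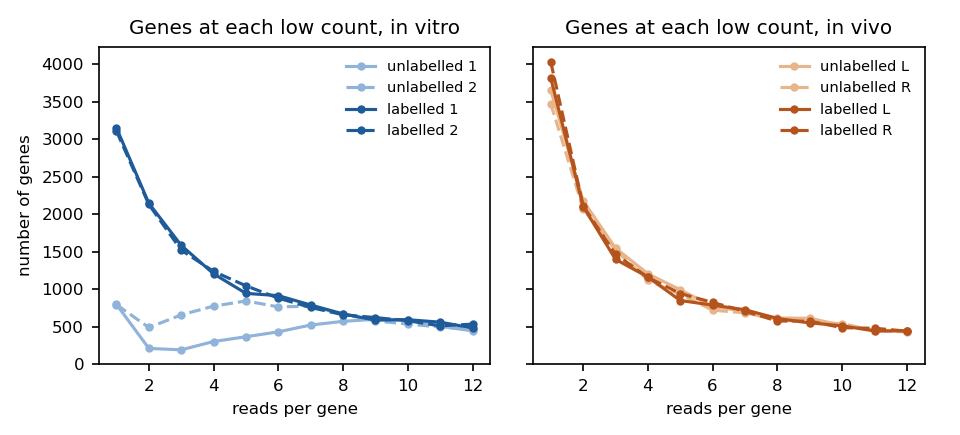
Number of genes (y axis) with each low read count from 1 to 12 (x axis), with a line per library, for culture in the left panel and xenografts in the right. The lines of unlabelled culture replicates 1 and 2 peak a second time at 9 and 5 reads; the lines of the other 6 libraries start at 3108 to 4028 genes with 1 read and fall from there.

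The genes of mitochondrial DNA took 4.92% ± 0.471 of all counts in unlabelled culture and 21.3% ± 2.62 in labelled culture (mean ± SD, n = 2 each), a difference of 16.4 points. In xenografts the share was 2.86% ± 0.296 without and 8.10% ± 1.01 with labelling, a difference of 5.24 points. The ratios of the means were 4.34 and 2.83. Both labelled libraries lay above both unlabelled libraries in each setting. The exact two-sided permutation test gave p = 0.333 in each setting, the smallest that 2 against 2 allows, and p = 0.0556 over both settings, the smallest of 36 arrangements. The single libraries held 5.25%, 4.59%, 19.5%, 23.2%, 2.65%, 3.07%, 7.38% and 8.82%, in the order of the totals above. Their 95% Wilson intervals, at most 0.0143 points on either side, cover the counting error of independent reads only. They are too narrow for unlabelled culture, where reads were piled up. The 13 mRNAs made up most of the share, with 4.42% ± 0.571 and 20.01% ± 2.86 in unlabelled and labelled culture and 2.82% ± 0.289 and 7.94% ± 1.00 in xenografts. The 2 mitochondrial rRNAs, MT-RNR1 and MT-RNR2, took 0.398% and 0.946% in culture and 0.0106% and 0.0408% in xenografts, and the tRNAs 0.0972%, 0.374%, 0.0287% and 0.120%.

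**Figure D2:**
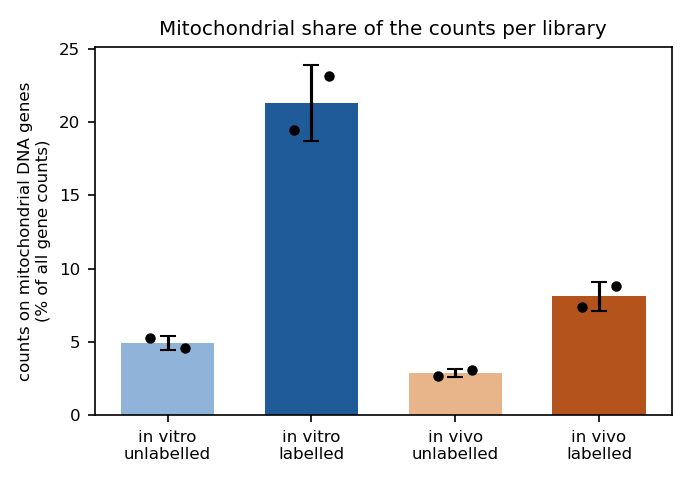
Share of all gene counts on the genes of mitochondrial DNA (y axis, percent) in the 4 groups (x axis); bars are group means with SD (n = 2) and points are libraries. Labelled libraries lie between 19.5% and 23.2% in culture and 7.38% and 8.82% in xenografts, above the unlabelled libraries of their setting, which lie between 2.65% and 5.25%.

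Labelling in culture raised every mRNA of mitochondrial DNA, which together encode subunits of the respiratory chain and of ATP synthase. The median of the 13 log2 fold changes was 2.54, from 2.19 ± 0.14 for MT-ND3 to 3.02 ± 0.16 for MT-CYB (± SE, n = 2 against 2). MT-CYB (ENSG00000198727.2), the cytochrome b gene at 14747 to 15887 of chromosome M (GRCh38, GENCODE release 44), went from 1772 ± 370 to 14385 ± 2421 CPM (adjusted p = 2.3e-06). MT-ND5, a complex I subunit at 12337 to 14148, rose by 2.32 ± 0.10 (adjusted p = 9.2e-07), and MT-ND6, on the minus strand at 14149 to 14673, by 2.7 ± 0.12 (adjusted p = 9.7e-07). The rRNAs rose less: MT-RNR1 (648 to 1601) by 1.93 ± 0.25 (adjusted p = 0.0013) and MT-RNR2 (1671 to 3229) by 0.82 ± 0.19 (adjusted p = 0.039). Of the 22 tRNAs, 19 rose, with a median of 2.13, and all 22 passed when adjusted over the list alone. The 3 not called over all genes were MT-TF (3.59 ± 0.97, adjusted p = 0.077), MT-TL1 (1.46, 0.14) and MT-TV (1.27, 0.29). MT-TF had 1 and 4 reads in unlabelled and 29 and 24 in labelled culture. Piled-up reads stood at 9 and 5 per gene in the unlabelled libraries, so its fold lies near the floor and its size is uncertain.

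In all, 34 of the 37 genes of mitochondrial DNA passed the edgeR test, all upward, and the AUC of their fold changes against 27863 nuclear genes was 0.991. As lists, the mRNAs (camera adjusted p = 1.33e-205), rRNAs (3.91e-05) and tRNAs (9.77e-133) were called upward; adjusted p = 0.0992, 0.326 and 0.083 with an estimated correlation. Without a filter on low counts 18 of the 37 were called, and the calls of MT-ND2 (adjusted p = 0.088), MT-ATP8 (0.059), MT-ATP6 (0.076), MT-RNR1 (0.24), MT-RNR2 (0.47) and 11 tRNAs were lost. The MT-RNR2 call was also lost with total counts (0.46, adjusted p = 0.094), with DESeq2 (adjusted p = 0.17), without labelled replicate 1 (0.50, adjusted p = 0.14) and after GC correction (0.74, adjusted p = 0.1). Because strand was not counted, reads of the opposite strand are part of each value, and reads in the overlaps of MT-ATP8 with MT-ATP6 and of MT-ND4L with MT-ND4 were dropped. The tRNA genes are 59 to 75 bases long and mostly adjoin other genes, and fragments that reached into a neighbour were dropped too. Values of the tRNAs in either setting therefore cover only fragments that touched no other gene, and may not follow the level of the tRNAs.

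**Figure D3:**
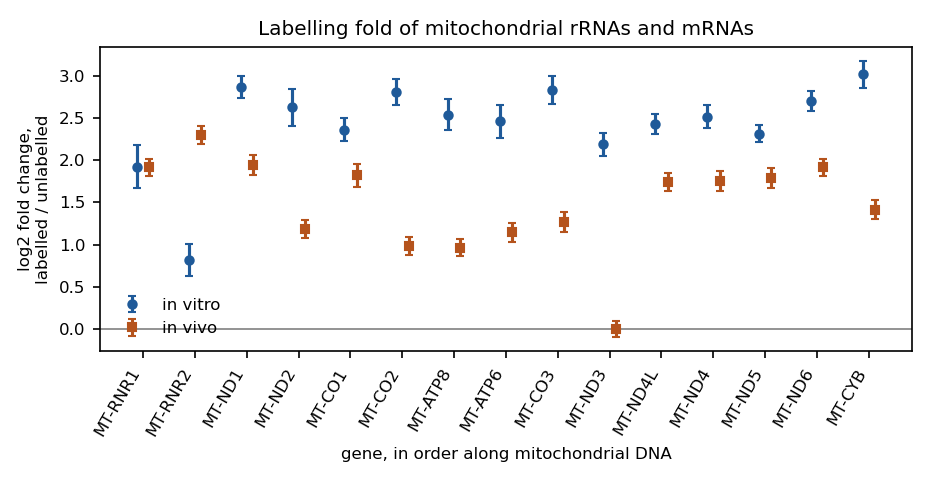
Log2 fold change of labelled over unlabelled libraries (y axis) for the 2 rRNAs and 13 mRNAs of mitochondrial DNA in their order along it (x axis); points are edgeR estimates with SE, circles for culture and squares for xenografts (2 against 2 libraries each). All 15 lie above 0 in culture, from 0.82 (MT-RNR2) to 3.02 (MT-CYB); in xenografts MT-ND3 lies at −0.01 and the others between 0.96 (MT-ATP8) and 2.30 (MT-RNR2).

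Across the genome, 979 of 27900 genes differed between labelled and unlabelled culture (877 higher, 102 lower, edgeR, adjusted p under 0.05), and 3924 had an unadjusted p under 0.05. Under the naming rule, the nuclear genes with the largest rises were mostly pseudogenes of mitochondrial DNA, copies of mitochondrial sequence in nuclear chromosomes: MTND1P23 (3.50 ± 0.26), MTCO3P12 (3.34 ± 0.19), MTND2P28 (3.34 ± 0.18), MTCO2P12 (3.31 ± 0.19), MTND4P12, MTATP6P1, MTND1P9, MTCO1P12 and MTND5P11. MTCO1P12, at 631074 to 632616 of chromosome 1, rose by 2.71 ± 0.13. RNVU1-15, a variant U1 small nuclear RNA, rose by 2.73 ± 0.33 (adjusted p = 0.00067), from 1.83 ± 1.06 to 12.04 ± 1.26 CPM. All 12 measured members of the list of mitochondrial pseudogenes rose (12 when adjusted over the list alone), with a median of 3.06 (camera adjusted p = 6.79e-110, adjusted p = 0.083 with an estimated correlation). Their reads and those of the mitochondrial genes can be exchanged by the aligner, so these values are uncertain. Falls were smaller. The largest under the same rule were in SLURP1 (−1.39 ± 0.27, adjusted p = 0.015), which encodes a secreted peptide, the histone gene H4C11 (−1.32 ± 0.32, 0.049), the protease gene TMPRSS9 (−1.32 ± 0.14, 0.00029) and the long noncoding RNA LINC00092 (−1.30, 0.036). H2AC13, a histone gene at 27808173 to 27808667 of chromosome 6, fell from 82.6 ± 2.58 to 37.6 ± 0.922 CPM (−1.13 ± 0.11, adjusted p = 0.00012).

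Single libraries and the filter mattered for these calls. Of the 979 calls, 629 were kept without labelled replicate 1 and 514 without labelled replicate 2. Without unlabelled replicates 1 and 2, 2411 and 4133 genes were called. SLURP1 was lost without labelled replicate 2 (−1.13, adjusted p = 0.3). H4C11 was lost without labelled replicate 1 (−1.53, 0.22) or 2 (−1.17, 0.64) and after GC correction (0.068). LINC00092 and ENSG00000287878, LINC01237, LINC01238 and UCKL1-AS1, which completed the 10 largest falls with H2AC21 (−1.09 ± 0.14, adjusted p = 0.001), were lost without either labelled replicate. With no filter 146 genes passed, and 62 of the 106 calls named by the rule were lost, TMPRSS9 among them (adjusted p = 0.099). Scaled to total counts only, the median of all genes shifted by −0.37 and 427 genes were higher and 5455 lower, so directions near 0 are relative to TMM.

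Genes for mitochondrial proteins that are encoded in the nucleus moved little next to the RNAs made in the organelle. Of 54 measured matrix enzymes 14 rose and none fell (18 and 1 when adjusted over the list alone). Among them were IDH3B of the citric acid cycle (1.23 ± 0.12, adjusted p = 0.00011), PDHA1 of pyruvate dehydrogenase (1.11 ± 0.10, 0.00011), DLD (0.97 ± 0.10, 0.00018) and the mitochondrial helicase gene TWNK (1.06 ± 0.10, 0.00015). The median of this list was 0.11, and −0.26 scaled to total counts (camera adjusted p = 8.75e-06, adjusted p = 0.533 with an estimated correlation). Of 59 subunits of oxidative phosphorylation 5 rose and 2 fell (7 and 3 adjusted over the list alone), with NDUFA8 at 1.13 ± 0.11 (adjusted p = 0.00012). Of 71 mitochondrial ribosomal proteins 4 rose (7 up and 3 down adjusted over the list alone), with MRPS26 at 1.14 ± 0.10 (8.7e-05). Neither list was called (camera adjusted p = 0.95 and 0.722). Their medians (−0.04 and −0.01) and means (0.01 and 0.03) differed in sign, and the tests pointed down and up. Scaled to total counts, 3 rose and 32 fell on the first (median −0.40) and 2 rose and 30 fell on the second (median −0.37). Among matrix enzymes 9 rose and 23 fell with that scaling.

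Other nuclear lists were called in culture. Of 30 measured histone genes 17 fell and 5 rose (20 and 5 adjusted over the list alone), with a median of −0.66. Camera called the list downward (adjusted p = 2.26e-09, and adjusted p = 0.408 with an estimated correlation). The risers were led by the H4 genes H4C2 (1.31 ± 0.10, adjusted p = 3.4e-05), H4C8 (1.18) and H4C5 (1.13). Without labelled replicate 1 the falls numbered 10, and with no filter 1. Of 18 heat shock genes 6 rose (10 adjusted over the list alone), led by AHSA1, an activator of HSP90 (1.72 ± 0.12, adjusted p = 1.1e-05). Their median was 0.34, and −0.03 scaled to total counts (camera adjusted p = 1.95e-07, adjusted p = 0.56 with an estimated correlation). Of these genes 3 rose without labelled replicate 2 and 10 without unlabelled replicate 1. Of 45 secretory pathway genes 10 rose (14 up and 3 down adjusted over the list alone). They included the disulfide isomerase gene PDIA6 (1.19 ± 0.10, 7e-05) and SEC61G of the translocon (1.32 ± 0.12, 9.3e-05). The list had a median of 0.03, and −0.33 scaled to total counts (camera adjusted p = 0.00234, adjusted p = 0.795 with an estimated correlation).

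Of 19 nuclear long noncoding RNAs 2 rose in culture (6 adjusted over the list alone). MALAT1 (ENSG00000251562.11), a nuclear speckle RNA at 65497640 to 65508073 of chromosome 11, went from 24.0 ± 1.91 to 95.1 ± 11.4 CPM (1.98 ± 0.13, adjusted p = 6.9e-06), and 1 member rose without unlabelled replicate 2 or labelled replicate 1. The list was called upward (median 0.07, and −0.30 scaled to total counts, camera adjusted p = 0.00581, adjusted p = 0.391 with an estimated correlation). Of 19 small nuclear RNAs 4 rose (4 up and 2 down adjusted over the list alone), including SCARNA7 (1.22 ± 0.10, 5.8e-05). This list was called upward (median 0.21, and −0.15 scaled to total counts, camera adjusted p = 0.0283, adjusted p = 0.408 with an estimated correlation). Without labelled replicate 1 or 2 the risers numbered 2. Of 30 S-phase genes 4 rose (5 adjusted over the list alone), led by the flap endonuclease gene FEN1 (1.00 ± 0.10, 0.00022). Their median was 0.14, and −0.23 scaled to total counts (camera adjusted p = 0.0011, adjusted p = 0.408 with an estimated correlation). Of 25 integrated stress response genes 3 rose (4 adjusted over the list alone), and 0 with no filter. Their median was 0.13, and −0.23 scaled to total counts (camera adjusted p = 0.0117, adjusted p = 0.391 with an estimated correlation). Cytosolic ribosomal proteins were called downward (median −0.16, camera adjusted p = 8.48e-05, adjusted p = 0.795 with an estimated correlation). Of the 78 members 2 rose and 2 fell (5 and 10 adjusted over the list alone), and RPL11 rose by 1.02 ± 0.10 (0.00016). DESeq2 called 5 of them higher and 24 lower, and 13 fell without unlabelled replicate 2 or labelled replicate 1.

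The remaining lists were not called in culture. Risers numbered 3 of 29 hypoxia targets (4 adjusted over the list alone, camera adjusted p = 0.368), 3 of 17 glycolysis genes (4 up and 4 down adjusted over the list alone, 0.386), 3 of 21 oxidative stress genes (3 up and 1 down adjusted over the list alone, 0.977). Risers also numbered 2 of 23 immediate early genes (2 adjusted over the list alone, 0.0785), 2 of 20 p53 targets (3 adjusted over the list alone, 0.0767) and 1 of 13 fibroblast markers (1 adjusted over the list alone, 0.508). None of these genes fell. LDHB, a lactate dehydrogenase subunit (0.98 ± 0.10, adjusted p = 0.0002), and the peroxiredoxin gene PRDX1 (0.81 ± 0.10, 0.00068) were among them. Single libraries moved these counts: without unlabelled replicate 1 the risers numbered 7 immediate early genes and 4 p53 targets. Without labelled replicate 1 they numbered 1 of each, and without labelled replicate 2 they numbered 1 hypoxia target. For the oxidative stress list the median (−0.13), the mean (0.00) and the upward test differed in sign. In 5 lists no gene passed the edgeR test: RNA polymerase III transcripts (median −0.22, mean 0.05, camera adjusted p = 0.368), G2/M genes (0.95) and the markers of endothelium (0.579), immune cells (0.484) and erythroid cells, muscle and skin (0.484). Of their 60 measured genes, 2 had an unadjusted p under 0.05 and DESeq2 called 0. Scaled to total counts, 14 of 30 G2/M genes were called lower (median −0.35), and 2 endothelial markers, 1 immune marker and 1 RNA polymerase III transcript.

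In xenografts, labelling raised 12 of the 13 mitochondrial mRNAs, both rRNAs and all 19 measured tRNAs (the same numbers adjusted over each list alone). The mRNAs had a median log2 fold change of 1.41 (n = 2 against 2). MT-ND1 (3307 to 4262) rose by 1.94 ± 0.12 and MT-ND6 by 1.92 ± 0.10 (adjusted p = 3e-23). MT-CO1, the catalytic subunit of cytochrome c oxidase at 5904 to 7445, rose by 1.82 ± 0.14, and MT-CO2 by 0.99 ± 0.11. MT-ND3 (ENSG00000198840.2), a complex I subunit at 10059 to 10404, stayed at 898 ± 61.3 CPM without and 895 ± 14.2 CPM with labelling (−0.01 ± 0.10, adjusted p = 0.998). The rRNAs rose more than most mRNAs, MT-RNR1 by 1.92 ± 0.10 (adjusted p = 5.4e-23) and MT-RNR2 by 2.30 ± 0.11 (4.6e-26), from 22.0 ± 5.20 to 109 ± 19.8 CPM for the latter. The tRNAs had a median of 2.46, from 0.65 ± 0.14 for MT-TT to 3.85 ± 0.27 for MT-TW.

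In all, 33 of 34 tested genes of mitochondrial DNA passed the edgeR test in xenografts and the AUC against 26416 nuclear genes was 0.983. The mRNAs (camera adjusted p = 7.21e-299), rRNAs (6.75e-92) and tRNAs (0 at the precision of the software) were called upward as lists, also with an estimated correlation (adjusted p = 0.0461, 0.0419 and 0.0419). The call of MT-ATP8 (0.96 ± 0.10) was lost with DESeq2 (adjusted p = 0.053) and in a single fit of all 8 libraries (0.093). That of MT-TT was lost with DESeq2 (0.12), without labelled library R (0.50, adjusted p = 0.69) and in the single fit (1). Each labelling group may be a single animal, so that labelling and animal cannot be told apart.

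Across all tested genes, 224 of 26450 differed between labelled and unlabelled xenografts (148 higher, 76 lower, 2263 at an unadjusted p under 0.05). The 33 called genes of mitochondrial DNA are among the 148. Under the naming rule, large rises were again in pseudogenes of mitochondrial DNA, such as MTCO3P12 (2.87 ± 0.23), MTND6P4 (2.64), MTCO1P12 (2.59 ± 0.11) and MTND2P28 (2.06). All 12 measured members of that list rose (12 adjusted over the list alone, median 2.04, camera adjusted p = 5.08e-190, adjusted p = 0.0419 with an estimated correlation). Large falls were in immediate early genes and their like: FOSB (−2.21 ± 0.24, adjusted p = 1.2e-10) and FOS (−1.85 ± 0.20, 1.2e-10), subunits of the AP-1 transcription factor. Others were the synaptic plasticity gene ARC (−1.47 ± 0.23, 6.5e-06), the MAP kinase phosphatase gene DUSP1 (−1.26 ± 0.15, 1.6e-09) and the matricellular protein genes CCN2 (−1.18 ± 0.17, 1.7e-06) and CCN1 (−1.08 ± 0.13, 3.6e-09). The ferritin heavy chain gene FTH1 fell by 1.17 ± 0.12 on the log2 scale (1.9e-11). The noncoding RNAs TSIX (−1.19 ± 0.10, 1.6e-14), which overlaps another gene on the opposite strand, and MIR222HG (−0.94 ± 0.09, 7.2e-12) fell under every alternative computed for them.

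Of 23 immediate early genes 13 fell in labelled xenografts and none rose (16 and 0 adjusted over the list alone), with a median of −0.60 (camera adjusted p = 1.29e-38, adjusted p = 0.328 with an estimated correlation). FOS was at 83.1 ± 61.1 CPM without and 23.3 ± 9.82 CPM with labelling, and library R lay above L in both groups: 130 and 40.7 CPM of total counts without, 29.9 and 15.8 CPM with labelling. Without unlabelled library R 5 of the 13 were called (median −0.17), and 13, 12 and 11 without unlabelled L, labelled L and labelled R; DESeq2 and the single fit of all 8 libraries called 1 each. DESeq2 gave FOS and FOSB adjusted p-values of 1 each, DUSP1 1, ARC 0.97, CCN2 0.99, CCN1 0.89 and FTH1 0.53. The single fit gave FOS 0.14, FOSB 0.16, ARC 0.46, DUSP1 0.16, CCN2 0.35 and CCN1 0.14. Without unlabelled library R the calls of ARC (−0.72, adjusted p = 0.13) and CCN2 (−0.59, 0.079) were lost as well.

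**Figure D4:**
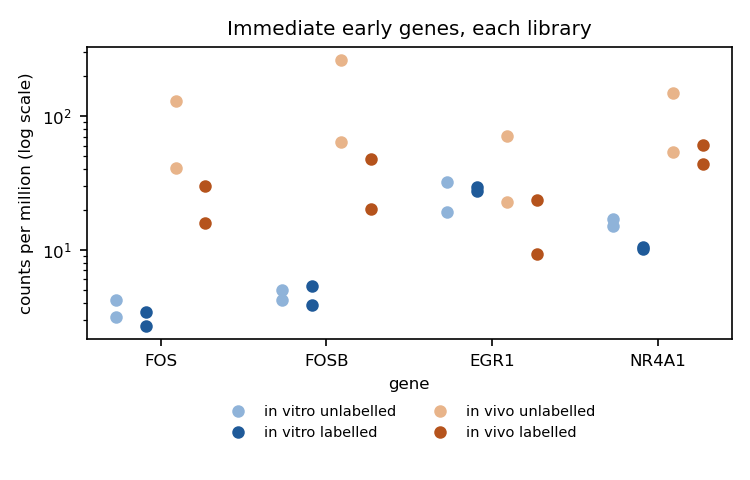
CPM of total counts (y axis, log scale) of FOS, FOSB, EGR1 and NR4A1 in the 4 groups, a point per library. FOS and FOSB lie below 6 CPM in all culture libraries; unlabelled xenograft library R is highest for each gene, with FOS at 130 and FOSB at 262 CPM.

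A few other lists were called in xenografts. Of 19 small nuclear RNAs 4 rose (10 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 7.37e-10, adjusted p = 0.195 with an estimated correlation). Among them were SNORD3A, the U3 small nucleolar RNA (0.51, adjusted p = 0.002), and RNU4ATAC of the minor spliceosome (0.80 ± 0.19, 0.012). None of the 4 was called without labelled library L or by DESeq2. Of 5 RNA polymerase III transcripts 1 rose (3 adjusted over the list alone, median 0.28, camera adjusted p = 0.000156, adjusted p = 0.601 with an estimated correlation). It was BCYRN1, a noncoding RNA of neurons (0.80 ± 0.14, 8.7e-05), and was lost without labelled library L (0.49, adjusted p = 0.47). The oxidative stress list was called downward (median −0.07, camera adjusted p = 0.000396, adjusted p = 0.475 with an estimated correlation) with FTH1 as the only call among 21 members (3 lower adjusted over the list alone). Cytosolic ribosomal proteins (median −0.07, camera adjusted p = 0.00222) and secretory genes (median −0.06, 0.0156) were called downward, with adjusted p = 0.893 for both with an estimated correlation.

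MALAT1 rose in xenografts too (1.01 ± 0.10, adjusted p = 3.1e-11), from 23.1 ± 2.27 to 46.3 ± 10.0 CPM. Of 19 nuclear long noncoding RNAs 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.307). The paraspeckle RNA NEAT1 fell (−0.55 ± 0.11, 0.0017), a call lost with DESeq2, in the single fit, and without unlabelled library R (−0.32, adjusted p = 0.1) or labelled library L (−0.38, adjusted p = 0.48). Of 54 matrix enzymes HSD17B10 (0.40 ± 0.09, adjusted p = 0.0043) and TWNK (0.38 ± 0.09, 0.011) rose (3 adjusted over the list alone). The list was not called (camera adjusted p = 0.846, median −0.01 and mean 0.00 with a downward test). Neither gene was called without labelled library L or R, with HSD17B10 at 0.39 (adjusted p = 0.31) and 0.42 (0.27). Single calls were made for H4C2 among 32 histones (0.47 ± 0.09, adjusted p = 0.00082, 1 adjusted over the list alone, camera adjusted p = 0.556) and the hormone gene STC2 among 29 hypoxia targets (0.36 ± 0.09, 0.024, 2 adjusted over the list alone, 0.49). Others were BTG2, an antiproliferative gene, among 20 p53 targets (−0.57 ± 0.11, 0.0011, 1 up and 1 down adjusted over the list alone, 0.295) and CD74, the invariant chain gene, among 4 immune markers (0.78 ± 0.20, 0.037, 1 adjusted over the list alone, 0.276). STC2 and ATF3 (−0.55 ± 0.11, 0.0012) were the calls among 24 integrated stress response genes (2 up and 2 down adjusted over the list alone, 0.846). DESeq2 called none of H4C2, STC2, BTG2, CD74 and ATF3. H4C2 was also lost without labelled library L (0.39, adjusted p = 0.3). BTG2 was lost without unlabelled R (−0.22, 0.3), ATF3 without unlabelled R (−0.17, 0.4) or labelled R (−0.46, 0.18). STC2 was lost without unlabelled R (0.21, 0.17), labelled L (0.41, 0.25) or labelled R (0.32, 0.93), and CD74 without unlabelled L (0.60, 0.31) or labelled R (0.60, 1.00).

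In 11 lists no member passed the edgeR test in xenografts. Beside the ribosomal protein and secretory lists these were the subunits of oxidative phosphorylation (camera adjusted p = 0.45), mitochondrial ribosomal proteins (0.155), glycolysis (0.144, 3 higher adjusted over the list alone), G2/M (0.494), S-phase (0.178) and heat shock genes (0.45). They also included the markers of fibroblasts (0.494, median −0.00, mean 0.05), endothelium (0.494, 1 higher adjusted over the list alone) and erythroid cells, muscle and skin (0.695). Of their 379 measured genes, 34 had an unadjusted p under 0.05 and DESeq2 called 0. Scaled to total counts 92 genes were higher and 125 lower in labelled xenografts. DESeq2 called 109 genes and the single fit 57, while 486, 138 and 109 genes were called without unlabelled R, labelled L and labelled R; without unlabelled L 245 genes were called, 112 higher and 133 lower.

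The interaction asked where the labelling effect itself differed between xenografts and culture. Mitochondrial mRNAs gained less in xenografts: 8 of 13 had a lower effect (13 adjusted over the list alone), with a median difference of −1.31 on the log2 scale (camera adjusted p = 7.87e-38, adjusted p = 0.39 with an estimated correlation). They included MT-ND3 (−2.19 ± 0.17, adjusted p = 3.5e-05), MT-CO2 (−1.82 ± 0.19, 0.00033), MT-CYB (−1.60 ± 0.21, 0.0016) and MT-CO3 (−1.56 ± 0.23, 0.0027), which were called with each library left out in turn. On the log2 scale MT-RNR2 went the other way (1.5 ± 0.29, adjusted p = 0.019). The rRNA list was called upward (median 0.75, 1 of 2 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.522 with an estimated correlation). In CPM of total counts MT-RNR2 gained less in xenografts, from 18.7 and 26.3 to 91.7 and 122, than in culture, from 1649 and 1202 to 2344 and 1571. Of 22 tRNAs 2 had a higher effect in xenografts and 2 a lower one, among them MT-TP (−1.72 ± 0.16, adjusted p = 0.00012, 4 and 2 adjusted over the list alone, camera adjusted p = 0.156).

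Across all genes the edgeR interaction was called for 462 of 29733 (33 with a higher effect in xenografts, 429 with a lower one, 3605 at an unadjusted p under 0.05). Nuclear genes with a lower effect included the splicing factor genes HNRNPA2B1 (−2.0 ± 0.12, adjusted p = 1e-05), HTATSF1 (−1.85 ± 0.13, 1.3e-05) and SNRPF (−1.82 ± 0.16, 9.1e-05). Others were the small GTPase gene RAB13 (−1.75 ± 0.21, 0.00067), RNVU1-15 (−2.20 ± 0.35) and the antiviral tetherin gene BST2 (−2.14 ± 0.33). HNRNPA2B1 (chromosome 7, 26171151 to 26201529) went from 1081 ± 76.2 to 4640 ± 32.9 CPM with labelling in culture and from 1401 ± 51.3 to 1507 ± 16.2 CPM in xenografts. Nuclear genes with a higher effect included RN7SKP255, a 7SK pseudogene (1.94 ± 0.34, adjusted p = 0.011), and CHGA, which encodes the granule protein chromogranin A (1.89 ± 0.31, 0.0069).

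Among the lists, 11 of 54 matrix enzymes had a lower effect in xenografts (1 higher and 13 lower adjusted over the list alone). Their median was −0.09, and 0.21 scaled to total counts (camera adjusted p = 3.23e-05, adjusted p = 0.626 with an estimated correlation). So had 8 of 45 secretory genes (12 adjusted over the list alone), with a median of −0.09, and 0.19 scaled to total counts (3.43e-05, adjusted p = 0.734 with an estimated correlation). AHSA1 (−1.56 ± 0.16) was among 2 of 18 heat shock genes with a lower effect (6 adjusted over the list alone, median −0.33, 3.43e-05, adjusted p = 0.734 with an estimated correlation). Pseudogenes of mitochondrial DNA had a median of −0.83, and 2 of 12 were lower (5 adjusted over the list alone, 3.23e-05, adjusted p = 0.522 with an estimated correlation). Of 23 immediate early genes 3 had a lower effect, JUN (−1.31 ± 0.25), CCN1 (−1.59 ± 0.33) and KLF6 (−0.70). The number was 12 adjusted over the list alone, with a median of −0.76 (6.41e-09, adjusted p = 0.626 with an estimated correlation). The count was 14 without unlabelled culture replicate 1, and 0 without labelled culture replicate 1, labelled xenograft L or labelled xenograft R. Histones were called upward with a median of 0.59 (2.5e-07, adjusted p = 0.626 with an estimated correlation). Of 33 histone genes 6 were higher and 4 lower (18 and 5 adjusted over the list alone). Cytosolic ribosomal proteins were called upward with a median of 0.14 (0.026, adjusted p = 0.878 with an estimated correlation), although 2 of 78 were lower and none higher (2 and 0 adjusted over the list alone). Scaled to total counts, 25 were higher and 2 lower, with a median of 0.42.

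Apart from the tRNAs, the lists not called for the interaction held few calls, all of a lower effect in xenografts. They numbered 2 each among the subunits of oxidative phosphorylation, mitochondrial ribosomal proteins, long noncoding RNAs, small nuclear RNAs, S-phase genes and oxidative stress genes, and 1 each among hypoxia targets, glycolysis and integrated stress response genes. Adjusted over the list alone, in the same order, 5, 2, 4, 4, 2, 3, 4, 2 and 4 were lower, and 1 each was higher among oxidative phosphorylation, small nuclear RNAs, hypoxia and glycolysis. NDUFA8 (−1.11), MRPS26 (−0.90), SCARNA7 (−1.0 ± 0.14) and LDHB (−1.05 ± 0.12) were among the lower genes. Scaled to total counts the calls were not all lower. Higher and lower calls then numbered 9 and 2 for oxidative phosphorylation, 7 and 2 for mitochondrial ribosomal proteins and 6 and 1 for glycolysis. Small nuclear RNAs stayed at 0 and 2. No gene was called on the lists of RNA polymerase III transcripts, G2/M genes, p53 targets and the markers of the 4 other tissues. Of their 99 genes, 12 had an unadjusted p under 0.05 and DESeq2 called 2 higher and 2 lower. Median, mean and test differed in sign for the uncalled lists of oxidative phosphorylation, small nuclear RNAs, oxidative stress, fibroblasts, endothelium and immune cells.

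The interaction rested on few libraries. It was called for 2575 and 3873 genes without unlabelled culture replicates 1 and 2, and for 213 and 156 without labelled culture replicates 1 and 2. The numbers were 204 and 193 without unlabelled xenografts L and R, and 152 and 126 without labelled xenografts L and R. MT-RNR2 was lost without labelled culture replicate 2 (1.25, adjusted p = 0.17), unlabelled xenograft L (1.28, 0.19) or R (1.77, 0.06), or labelled xenograft R (1.30, 0.14). Of the 69 calls named by the rule, 40 were lost without labelled xenograft R, 35 without labelled xenograft L, and 29 and 33 without unlabelled xenografts L and R. Without labelled culture replicates 1 and 2, 23 and 36 were lost. Over the libraries left out in turn, the lower calls numbered 4 to 13 among mitochondrial mRNAs and 4 to 17 among matrix enzymes, and the higher calls 0 to 17 among histones. CHGA was lost without labelled culture replicate 2 (1.82, adjusted p = 0.071), unlabelled xenograft L (1.80, 0.064) or labelled xenograft R (1.75, 0.079). RNVU1-15 was lost without labelled culture replicate 2 (−2.08, 0.073), unlabelled xenograft R (−2.12, 0.063) or labelled xenograft R (−2.17, 0.052). BST2 was lost without labelled xenograft R (−2.05, 0.059), and RN7SKP255 without labelled culture replicate 2 or any xenograft library (1.79 to 2.03, adjusted p from 0.06 to 0.11). Scaled to total counts, the median of all genes shifted by 0.29 and 1556 genes had a higher and 278 a lower effect in xenografts.

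Unlabelled libraries of the settings were compared to describe the background of RNA that labelling was read against. Xenograft libraries held fewer counts of mitochondrial rRNA, with MT-RNR2 at 22.9 ± 5.41 CPM against 1410 ± 357 CPM in culture (−5.94 ± 0.23, adjusted p = 1.1e-05). MT-RNR1 was lower by −4.88 ± 0.29 (2.8e-05). Ribosomal RNA was depleted before sequencing, and whether depletion differed between the settings was not tested. Of 21 mitochondrial tRNAs 19 were lower, with a median of −2.24, also with the undetected members at their bound. These tRNA values cover only fragments that touched no other gene. Taking a floor of 3 counts per library, MT-TL1, with 5.03 CPM of total counts in culture, was at least 51.7-fold lower in xenografts (21.7-fold without culture replicate 2, 81.7-fold without replicate 1). MT-TV, with 0.833 CPM of total counts, was at least 8.56-fold lower, a call lost without either unlabelled xenograft library (adjusted p = 0.057 without L and 0.056 without R). In unlabelled culture MT-TV had 33 and 20 reads, where reads were piled up at 9 and 5 per gene, so its bound rests on few molecules. Of 13 mitochondrial mRNAs 7 were lower, such as MT-CO1 (−0.94 ± 0.13, adjusted p = 0.0006), and MT-ND3 was higher (0.58 ± 0.12, 0.0056, and 0.17 after GC correction, adjusted p = 0.3). Listed pseudogenes of mitochondrial DNA were lower for 7 of 12, such as MTCO1P12 (−1.72 ± 0.16). All 4 lists, rRNAs, tRNAs, mRNAs (median −0.43) and pseudogenes (median −1.19), were called downward, with camera adjusted p = 4.78e-15, 5.22e-15, 0.00707 and 0.00676. In the same order, adjusted p = 0.322, 0.322, 0.677 and 0.322 with an estimated correlation. The numbers adjusted over the list alone were 2, 19, 7 and 7 lower, and 1 mRNA higher. The median of the mRNAs was −0.7 after GC correction.

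In all, 10143 of 28260 genes differed between unlabelled xenografts and culture (4830 higher, 5313 lower, edgeR). Immediate early genes were higher in xenografts (13 of 23 higher, 1 lower, median 0.80), led by FOSB (5.19 ± 0.59, adjusted p = 0.00028), FOS (4.57 ± 0.49, 0.00023) and the nuclear receptor gene NR4A1 (2.69 ± 0.38). Unlabelled xenograft R carried much of this, and without it FOSB was at 3.83, FOS at 3.51 and NR4A1 at 1.78, 10 were higher (median 0.57), and EGR3 (2.53, adjusted p = 0.016) lost its call (adjusted p = 0.26). Hypoxia targets were higher as well (18 of 29 higher, 1 lower, median 0.58), with the repressor gene BHLHE40 (1.90 ± 0.12, 3.7e-05), the pyruvate dehydrogenase kinase gene PDK1 (1.43 ± 0.12) and the glucose transporter gene SLC2A3 (2.02 ± 0.19). G2/M genes (22 of 30 higher, 1 lower, median 0.56) were higher, with the cytokinesis gene ECT2 (1.14 ± 0.10) and the kinesin gene KIF11 (1.10 ± 0.11). Nuclear long noncoding RNAs (12 of 19 higher, 1 lower, median 0.41) included FIRRE (1.68 ± 0.14) and NEAT1 (1.47 ± 0.14), and histones (17 of 33 higher, 1 lower, median 0.47) included H4C3 (0.73 ± 0.09). Camera gave these lists adjusted p-values of 9.29e-05, 6.83e-10, 1.23e-08, 3.69e-05 and 0.000216 in this order; adjusted p = 0.66, 0.322, 0.421, 0.322 and 0.633 with an estimated correlation. Adjusted over the list alone, 14, 19, 23, 12 and 19 were higher and 1, 2, 1, 1 and 1 lower. After GC correction the median was 0.25 for G2/M genes, with 13 of 30 higher, and 0.23 for long noncoding RNAs, with 9 of 19 higher.

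Further lists were called upward. Of 20 p53 targets 8 were higher and 3 lower (median 0.30), with the p53 antagonist gene MDM2 at 1.48 ± 0.09 (adjusted p = 3.7e-05). Of 17 glycolysis genes 5 were higher and 1 lower (median 0.18), with the hexokinase gene HK2 at 1.10 ± 0.10. Mitochondrial ribosomal proteins had 19 of 71 higher and 3 lower (median 0.12), with MRPL15 at 1.11 ± 0.10. Matrix enzymes had 26 of 54 higher and 10 lower (median 0.16), with the mitochondrial transcription factor gene TFAM at 0.84 ± 0.11 and TWNK at −0.83 ± 0.11. In this order, camera adjusted p-values were 0.00473, 0.0142, 0.00725 and 0.0325, and adjusted p = 0.409, 0.677, 0.633 and 0.677 with an estimated correlation. Called downward were integrated stress response genes (2 of 24 higher, 11 lower, median −0.37), with CHAC1, a glutathione-degrading enzyme, at −3.35 ± 0.38 and SESN2 at −1.62 ± 0.11. So were RNA polymerase III transcripts (1 of 5 higher, 3 lower, median −0.78), with RN7SL1 of the signal recognition particle at −1.36 ± 0.18. Camera gave adjusted p = 0.00473 and 0.011, and adjusted p = 0.322 and 0.633 with an estimated correlation. Adjusted over the list alone, 9, 5, 19, 26, 2 and 1 of these 6 lists were higher and 3, 1, 3, 10, 11 and 3 lower. GC correction moved glycolysis to 13 of 17 higher with a median of 0.43, and p53 targets and mitochondrial ribosomal proteins to medians of 0.45 and 0.18. It gave 14 matrix enzymes higher and 2 lower, and moved the integrated stress response to a median of −0.20.

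Markers of endothelium, of immune cells, and of erythroid cells, muscle and skin were lower in xenografts. Counted on human gene models, with the handling of mouse reads unknown, they do not show how much host tissue was present. They were lower for 7 of 9 endothelial markers (median −1.42), 5 of 7 immune markers (median −2.12) and 6 of 10 erythroid, muscle and skin markers, of which 1 was higher (median −2.09). Camera gave adjusted p = 0.000216, 0.00176 and 0.0197, and adjusted p = 0.322, 0.322 and 0.352 with an estimated correlation. With GC correction 4 markers of each of these 3 lists were called lower, and 1 endothelial marker was higher. The tight junction gene CLDN5 went from 17.7 ± 3.57 CPM in culture to 0.705 ± 0.135 CPM in xenografts (−4.66 ± 0.26), and CD74 (−3.19 ± 0.21) and the creatine kinase gene CKM (−3.77 ± 0.42) were lower too. Fibroblast markers had 3 of 15 higher and 7 lower (median −0.42, and 0.07 after GC correction, mean 0.51, camera adjusted p = 0.183). The collagen gene COL1A2, at 0 counts in both unlabelled culture libraries and 2.65 CPM of total counts in xenografts, was at least 4.03-fold higher, with a floor of 3 molecules of 9 and 5 reads each in these libraries. The bound was 2.28-fold without unlabelled xenograft R and 5.78-fold without L. Without unlabelled xenograft L, and likewise without R, 3 endothelial, 3 immune and 3 erythroid, muscle and skin markers were called lower. Adjusted over the list alone, 7, 5, 7 and 7 of these 4 lists were lower and 0, 0, 1 and 3 higher.

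The other lists were not called. These were subunits of oxidative phosphorylation (11 of 59 higher, 7 lower, camera adjusted p = 0.522), cytosolic ribosomal proteins (16 of 78 higher, 6 lower, 0.211), and small nuclear RNAs (5 of 20 higher, 1 lower, 0.398). They also included secretory genes (11 of 45 higher, 8 lower, 0.722), S-phase genes (11 of 30 higher, 3 lower, 0.0811), oxidative stress genes (5 of 21 higher, 8 lower, 0.562) and heat shock genes (3 of 18 higher, 2 lower, 0.635, median −0.06, with an upward test). Adjusted over the list alone, 10, 15, 5, 13, 11, 5 and 3 were higher and 7, 6, 1, 9, 3, 9 and 2 lower. Single genes with a lower level in xenografts included LINC01348 (−5.16 ± 0.24, chromosome 1, 235064927 to 235074220), a long noncoding RNA, and ZP1, an egg coat protein gene (−4.23 ± 0.33). Higher were, among others, the U5 small nuclear RNA RNU5D-1 (4.20 ± 0.25) and the sulfotransferase gene SULT1C4 (3.03 ± 0.31). Without unlabelled xenograft L 4343 genes were called and without R 5823, against 14819 and 15652 without unlabelled culture replicates 1 and 2. Without unlabelled xenograft L the higher calls numbered 6 histones, 7 long noncoding RNAs, 9 matrix enzymes, 10 mitochondrial ribosomal proteins and 5 p53 targets. After GC correction 7576 genes were called, 5672 of the 10143 among them. The fold went with transcript GC content (Spearman −0.672 across 11437 nuclear genes, which are not independent replicates). Both unlabelled culture libraries had piled-up reads and the xenograft libraries did not. Setting cannot be told apart from these traits of the libraries, nor from host, dose and handling.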

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

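The tests on added unlabelled reads, gene length, labelling chemistry and a single library were chosen only after the results they bear on had been seen; those on the animal were set before. The results gathered here stood out because the labelling effect differed between xenografts and culture in the test of that difference, edgeR's interaction term, which called 462 genes. All values are log2 labelling effects in xenografts minus culture. Of the 68 genes given here 23 kept the call with each library left out in turn, and 10 lost it without each of the 6 libraries other than unlabelled culture (adjusted p from 0.0516 to 0.314). With an estimated correlation 0 of the 9 list calls held.

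The mitochondrial mRNAs gained less in xenografts, with a list median of −1.31: MT-ND3 −2.19, MT-CO2 −1.82, MT-CYB −1.60, MT-ATP8 −1.57, MT-CO3 −1.56, MT-ND2 −1.43, MT-ATP6 −1.31 and MT-ND6 −0.78. MT-ND6 lost the call without each of the 6 libraries other than unlabelled culture (adjusted p from 0.0569 to 0.219) and scaled to total counts (0.0663). MT-ND2 and MT-ATP6 lost it without 5 of them (up to 0.165 and 0.169) and MT-ATP8 without 4 (up to 0.0999). Reads without label, from mouse RNA or carry-over, would add equally to both groups and leave the differences in CPM in proportion. The ratio of the difference in xenografts to that in culture had a median of 0.261 over the 13 mRNAs, and for 12 of them it lay, within its standard error, between 0.5 and 2 times that value. MT-ND3 (−0.0283 ± 0.0289) lay outside. That range is wide, and the other 12 ratios ran from 0.130 ± 0.0215 for MT-CO2 to 0.498 ± 0.0860 for MT-ND4L. The differences were thus not in strict proportion, which added reads alone would leave. As a part of the difference, added reads cannot be told apart from a lower labelling effect. Poor counting of short genes would give the 3 shortest mRNAs the lowest values, but MT-ND4L, among these 3, lay at −0.67 ± 0.17, above the median. An effect of the animal cannot be told apart from that of labelling, because 0 libraries of either labelling group are known to come from another animal than their partner. A biological difference between tumour and culture may be part of it and was not tested.

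Of 23 immediate early genes 13 fell with labelling in xenografts, 1 with DESeq2 and 1 in the single fit of 8 libraries. The list had a median difference between settings of −0.76, and 3 of the 23 were called, CCN1 at −1.59, JUN at −1.31 and KLF6 at −0.70. With an estimated correlation neither list call held (adjusted p = 0.328 and 0.626). CCN1 and KLF6 lost the call without 5 of the libraries (adjusted p from 0.0957 to 0.224). An action of the labelling chemistry on these transcripts was argued against for the doses used in culture only. The 13 members that fell in xenografts had a median of −1.08 there. In culture their lower quartile was at 0.10, and at −0.27 when shifted to total counts. An action at the xenograft doses stays open, since doses differed and FOS lay at only 2.69 to 4.20 CPM of total counts in culture. A single unlabelled library could account for much of the pattern, since without unlabelled xenograft R 5 of the 13 stayed called. The animal or the handling of its tumours before collection cannot be told apart from labelling, because 0 libraries of either group are known to come from another animal than their partner.

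Other genes of mitochondrial DNA and their pseudogenes differed as well: MT-TQ 1.98, MT-TI 1.74, MT-RNR2 1.5 (rRNA list median 0.75), MT-TT −2.06, MT-TP −1.72, MTCO2P12 −1.5 and MTND2P28 −1.27 (pseudogene list median −0.83). MT-TQ and MT-TT lost the call without each of the 6 libraries other than unlabelled culture (adjusted p from 0.0644 to 0.264 and from 0.077 to 0.192), and MT-TI without 5 of them (0.138 to 0.308). An effect that is higher in xenografts is not by itself a rise there. TMPRSS9, H2AC21 and UCKL1-AS1 were among the largest falls named in culture. Nuclear genes with a higher effect in xenografts were RN7SKP255 1.94, CHGA 1.89, RN7SKP80 1.37, UCKL1-AS1 1.19, TMPRSS9 1.13, ACP4 1.07, FAM27E3 1.04, YJEFN3 1.01, H2AC21 0.97 and DTX2 0.95. Each of these 10 lost the call without 3 or more libraries. UCKL1-AS1, YJEFN3 and DTX2 lost it without each of the 6 other than unlabelled culture (adjusted p up to 0.314), as did PALM3, SNHG22, CEBPG and DNAJA1 of the genes that follow. RN7SKP255, RN7SKP80, TMPRSS9, ACP4 and FAM27E3 lost it without 5 (adjusted p up to 0.262). DESeq2 gave no adjusted p for MT-TQ, MT-TI, UCKL1-AS1, RN7SKP255, CHGA, BST2, PALM3, RN7SL15P, SNHG22 and RNU4-2. Those with a lower effect were RNVU1-15 −2.20, BST2 −2.14, HNRNPA2B1 −2.0, PALM3 −1.98, RN7SL15P −1.96, HTATSF1 −1.85, SNRPF −1.82, SNHG22 −1.80, RAB13 −1.75 and RNU5D-1 −1.74. Among mitochondrial proteins the values were IDH3B −1.22, NDUFA8 −1.11, PDHA1 −1.09, DLD −0.96, PDHB −0.92, COX6C −0.91, MRPS26 −0.90 and MRPL51 −0.78, with a median of −0.09 for matrix enzymes. RPL22 and RPL11 had −1.10 and −0.83 while the cytosolic ribosomal protein list had a median of 0.14. Noncoding RNAs were RNU4-2 −2.14, SCARNA7 −1.0, MALAT1 −0.96 and NEAT1 −0.91, and RNU4-2, MALAT1 and NEAT1 lost the call without 5 libraries (adjusted p up to 0.222, 0.197 and 0.259). Histones were H4C5 −1.02, H4C8 −0.98, H2AC13 0.95 and H3C10 0.88, with a list median of 0.59. Secretory genes were SEC61G −1.10, INSIG2 (of the hypoxia list) −0.95, PDIA6 −0.92, SPCS2 −0.89 and SEC11A −0.74, with a secretory list median of −0.09. Stress and metabolic genes were AHSA1 −1.56, LDHB −1.05, FEN1 −0.84, TXNRD1 −0.80, DNAJA1 −0.68, PRDX1 −0.67 and CEBPG −0.60, with a heat shock list median of −0.33. PRDX1, and the pseudogenes MTND2P28 and MTCO2P12, lost the call without 5 libraries (adjusted p up to 0.108, 0.183 and 0.31).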

How the results depend on the processing

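Division of piled-up counts (collapsed copies), GC correction and blocks on the letters L and R were chosen after seeing the data; the other alternatives were planned. Where a value moved, the cause was not tested, except that a stricter or absent filter changes how many genes are tested and a minimum fold removes calls by construction. Without a library the lone sample of its group is assumed to vary like the others.

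Called genes in culture numbered 979, and 5882 with total counts only, 146 with no filter, 1555 with a CPM filter, 1640 with DESeq2, 2023 in the single fit of 8 libraries, 1792 with collapsed copies, 231 at a minimum fold and 529 to 4133 without single libraries. In xenografts they numbered 224, and 109 with DESeq2, 57 in the single fit, 83 at a minimum fold and 109 to 486 without single libraries. The interaction gave 462, and 1834 with total counts, 1052 with no filter, 891 with DESeq2, 932 with collapsed copies, 692 with GC correction and 126 to 3873 without single libraries. Xenograft against culture gave 10143, and 4343 to 15652 without single libraries. Genes of mitochondrial DNA called in culture fell to 18 with no filter and numbered 33 to 36 otherwise, and 31 to 34 in xenografts.

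The AUC in culture, 0.991, was 0.997 with a CPM filter, 0.998 from folds of mean CPM and 0.951 to 0.992 without single libraries; in xenografts, 0.983, it was 0.984 with a CPM filter and 0.975 to 0.984 without single libraries. The share differences of 16.4 and 5.24 points ranged from 14.6 to 18.3 and 4.52 to 5.95 without single libraries and stayed upward without rRNAs or over protein-coding genes alone. With an estimated correlation, 0 of 13 lists called in culture, 4 of 10 in xenografts, 0 of 9 for the interaction and 0 of 18 for xenograft against culture stayed past the threshold.

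Of 7971 alternative values of 569 named results, each a gene in 1 comparison, 7197 kept direction and side of the threshold, 466 lost and 305 gained a call and 3 reversed: MT-RNR1 in the interaction without unlabelled culture replicate 2 (−0.54; 0.39 without replicate 1), and MT-TP (−0.69) and CHORDC1 (−0.14) in xenograft against culture after GC correction.

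In culture the replicate numbers were shared by labelled and unlabelled libraries, but differences between replicates 1 and 2 did not go together (Pearson 0.0021, Spearman 0.008, across 11389 genes, which are not independent replicates). With the replicate block 1479 genes and 35 of mitochondrial DNA were called, the AUC was 0.985 and 12 lists were called (small nuclear RNAs lost, adjusted p = 0.0556). The xenograft columns carry the letters L and R in place of numbers, and nothing in the labels ties them across labelling groups (Pearson −0.174 for L minus R, across 11271 genes). With the letters as replicate block 211 genes were called in xenografts, 33 of mitochondrial DNA among them, and 408 with L set against R; with numbers and letters the interaction gave 349 and 10 lists, RNA polymerase III transcripts added (adjusted p = 0.0211). No paired analysis was possible because the columns of the settings share no numbers, for xenograft against culture. Depth limits low counts: in unlabelled culture replicates 1 and 2 the piled-up reads, at 9 and 5 per gene, stand for fewer independent molecules than their totals.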

Other observations

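The tests of GC content and of piled-up copies were chosen only after the result was seen; the test of purine content in long noncoding RNAs was set before its result was seen. The heterogeneous nuclear ribonucleoproteins (HNRNP), which bind and splice nascent transcripts, were chosen as a group after their values were seen. In culture 17 of 21 HNRNP genes rose and none fell (median log2 fold change 1.25; 15 rose and 2 fell scaled to total counts, median 0.89), led by HNRNPH3 (2.13 ± 0.10, edgeR adjusted p = 1.1e-06), HNRNPA2B1 (2.12 ± 0.10, 1.1e-06) and HNRNPA3 (1.99 ± 0.10, 1.1e-06). In xenografts 3 of 21 rose (median 0.16; 1 scaled to total counts), namely HNRNPM (0.38 ± 0.09), HNRNPH3 (0.38 ± 0.09) and HNRNPA3 (0.35 ± 0.09), and the interaction called 16 of 21 lower in xenografts (median −1.14). Because the group was chosen after its rise in culture was seen, and the interaction subtracts that rise, these 16 calls are not a separate result. The nucleolar protein gene NCL, chosen after its value was seen, rose by 1.96 ± 0.10 in culture.

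Of the nuclear genes other than mitochondrial pseudogenes, 816 that rose in culture and 89 that rose in xenografts were tested in both, and 41 rose in both, against 2.904 for independent lists (n1 × n2 / N; Fisher's exact test across 25008 genes, which are not independent replicates, p = 3.9e-37). Among these, chosen after their values were seen, were MALAT1, the RNA-binding protein gene TAF15 (1.43 ± 0.11 in culture and 0.78 ± 0.09 in xenografts), the nucleosome-binding protein gene HMGN5 (2.13 ± 0.14 and 0.65 ± 0.09), RAB13 (2.35 ± 0.18 and 0.59 ± 0.13), whose mRNA is known to localise to cell protrusions, and the fibrillarin gene FBL (1.43 ± 0.11 and 0.40 ± 0.09). The number 2.904 takes all tested genes as equally likely to be called, whatever their level, so it may be too low. Of 100 such genes that fell in culture and 72 that fell in xenografts, 0 fell in both, against 0.288 for independent lists.

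The 817 nuclear genes that rose in culture had a median log2 fold change of 0.68. GC content of the transcript as the whole cause was argued against, since the median was 0.65 after GC correction and 789 of the 817 stayed called. Piled-up copies in the unlabelled culture libraries were argued against as the whole cause as well, since 598 of 816 (73.3%) were higher in labelled xenografts, whose libraries show no such copies, against 46.9% of 10480 other nuclear genes. Their median in xenografts was 0.07, so copies as a part of the size in culture stay open. A hypothesis that stays open is that purine-rich RNA gained more counts in the labelled culture: the rank correlation of purine content and fold change was 0.358 across the coding sequences of 10627 genes and 0.128 across 466 long noncoding RNAs, above the bound of 0.1 set beforehand, but −0.0168 across coding sequences in xenografts. After GC correction the values across coding sequences were 0.257 in culture and 0.0993 in xenografts (genes are not independent replicates). Unlabelled xenografts against unlabelled culture gave 0.276, and 0.0242 after GC correction, with no labelling on either side. A trait of the unlabelled culture libraries may thus be part of the 0.358. No biological explanation was tested, and purine content may stand for another property of these transcripts.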
